A study of Drosophila melanogaster with 2 samples.

How the data were processed

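ChIP-seq was done on whole embryos that expressed Atf-2 fused to GFP from a transgene, with an antibody to GFP, after sonication and selection of fragments of 200 to 800 bp, per the labels' protocols. The samples are biological replicates 2 and 3 of this one group, aged 0 to 24 h; a replicate 1 and the control samples were not analysed here. What was used are 4 peak lists on each of the builds dm6 and dm3: a list for each replicate, a list called on the pooled replicates, and a list thresholded on the irreproducible discovery rate (IDR). Per the deposited readme texts, each replicate list was derived from the replicate's alignments and a control, the pooled list from the alignments of both replicates and a control, and the IDR list from the replicate lists and the pooled list. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here.

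The signal of each peak is the value that the authors' peak caller wrote for it, and it was used only to rank, filter or describe peaks. The deposited lists also hold a −log10 q-value per peak, which was tied at its maximum for all IDR peaks on dm6 and was therefore not used for ranking. The pooled and replicate lists hold 30000 regions each and include background, so presence in them is not a call. On dm6 all 3265 IDR peaks were found in the pooled list with the same interval and signal, and they were its 3265 strongest regions. They occupy 3255 distinct intervals, 10 of which carry 2 summits. The smallest IDR signal was 84.6, and the median interval was 436 bp. No read totals enter these lists, so depth is unknown and could not be used to weigh the replicates.

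Everything computed here was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The dm6 lists were read against the Release 6 sequence and the Ensembl release 115 annotation, on chromosomes 2L, 2R, 3L, 3R, 4 and X; every interval fell inside these sequences. The dm3 lists were used for counts only and no coordinate was converted. Coordinates are printed with counting from 1. A region overlapped another if they shared 1 bp, and where several did, the one of highest signal was taken. Summits were assigned to 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron or intergenic sequence in that order. A promoter peak had its summit within 500 bp of an annotated TSS of a protein-coding gene. One peak can count for several neighbouring genes, as at divergent promoters.

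Promoter and coding shares were set against 1000 random placements with the same number of positions per chromosome, with one-sided permutation p-values. Motifs were sought on both strands in windows of 100 bp on each side of the summit, against up to 2 windows per peak placed 2000 bp away that overlapped no IDR peak, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 12 motifs or over all 8-mers. Gene lists (26) and noncoding classes (4) were tested the same way, against other protein-coding genes on the same chromosomes, with adjustment over the lists or classes. Peaks and genes, not embryos, are the units of these tests, so p-values describe these lists and not the variation between embryos. The motifs, the lists, the tests and most alternatives were fixed before the data were examined. The genes named are those nearest to the 20 strongest peaks, every member of the p38, JNK and bZIP lists with a promoter peak and Atf-2 in any case, the 4 members with the strongest promoter peak in each other list that passed the test, and the 10 leading 8-mers; members of lists that did not pass were named after their values were seen. An item that this rule would name is not reported here.

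The tests were tried on simulated data. With a CRE planted in 5% of windows at random positions, the motif test called the CRE in 20 of 20 simulations and other motifs in 1 of 220 tests, and the 8-mer scan ranked it 1 in each of 3 scans. Up to 11 other 8-mers were called in such a scan. The planted share is far above the 0.49% of real peak windows with a CRE, so power for a modest enrichment was not tried. Random positions also carry no GC difference between peaks and flanks. With 60% of ribosomal protein genes and 15% of all others marked as bound, the list test called that list in 20 of 20 simulations and other lists in 0 of 500 tests over 13945 genes. These shares are close to the observed 62.0% and 14.6% for that list of 92 genes. Genes were drawn independently, and power for the small lists was not tried. Random peaks gave promoter shares of 10.8 to 12.2%.

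Alternatives covered the strongest 3265 regions of each replicate alone, the stronger 1632 IDR peaks, other promoter distances and windows, an overlap of 50% in both directions, only the outermost TSS, the other pooled regions as background, genes with any pooled region near a TSS as background, and the dm3 lists. Alternatives added after seeing the data were flanks matched on GC content, promoter peaks against promoters without a peak, the replicate overlap on dm3, and all those of the coding share. The split of the replicate overlap by peak strength and the random draws of fewer flanks were also made after seeing the data.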

Results

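Binding of Atf-2 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos of Drosophila melanogaster aged 0 to 24 h, from both sexes. Atf-2 is a basic leucine zipper (bZIP) transcription factor that is phosphorylated by the stress kinase p38, and relatives of it bind the cAMP response element (CRE), TGACGTCA. The flies carried a transgene for Atf-2 fused to green fluorescent protein (GFP) at its C-terminal end, and chromatin was recovered with an antibody to GFP. The only group consisted of 2 biological replicates, numbered 2 and 3, so no comparison between conditions was possible. The comparisons below set the replicates against each other, and the peaks against the rest of the genome. Read totals are not part of the peak lists, so the depth of each sample is unknown and peak signals carry no counting interval. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals and cover counting error over peaks or genes only.

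Both replicates placed their strongest Atf-2-GFP signal at the same sites. On build dm6 the list thresholded on the irreproducible discovery rate (IDR list) contained 3265 peaks, which were the 3265 strongest regions of the pooled list, and the same list on build dm3 contained 3062. The 20 strongest peaks of the IDR list were also the 20 strongest regions of replicate 2 and the 20 strongest of replicate 3. The strongest peak lay on chromosome 2L at 480843 to 481323, in an intron of ush, which encodes a cofactor of GATA factors, and 1380 bp from the nearest transcription start site (TSS), that of cbt, a zinc finger transcription factor gene. Its signal was 1965 in the pooled list, 1321 in replicate 2 and 634 in replicate 3. The peak ranked 2, on chromosome X at 1276464 to 1277342, lay upstream of Atf3, another bZIP factor, with signals of 1913 pooled, 1022 in replicate 2 and 885.5 in replicate 3.

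Of the 3265 IDR peaks, 2970 (91.0%) overlapped one of the 3265 strongest regions of replicate 2, 2651 (81.2%) one of the 3265 strongest of replicate 3, and 2390 (73.2%) did both. The IDR list was derived from both replicates and held the strongest pooled regions, so these overlaps and the correlation below are raised by that selection. The overlap of the replicates' own 3265 strongest regions with each other is not given here. The share in both was 100% in the strongest 653 peaks and 21.7% in the weakest 653. Peaks near a shared cutoff drop out first by construction, but with 2 times as many of the strongest regions of each replicate the share was still 84.7% in the weakest 653 against 100% in the strongest, and 94.6% overall. In replicate 3, 3254 of the 3265 peaks had a region of any rank. Across the 3254 IDR peaks with a region of any rank in both replicates, Spearman's rho of the signals was 0.70 and Pearson's r of log2 signal was 0.79, a correlation across peaks and not across samples. The signal in replicate 2 was a median 1.93 times that in replicate 3, with an SD of 0.51 on the log2 scale across peaks. The lists were not scaled to each other, so this ratio is not a difference in binding.

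**Figure D1:**
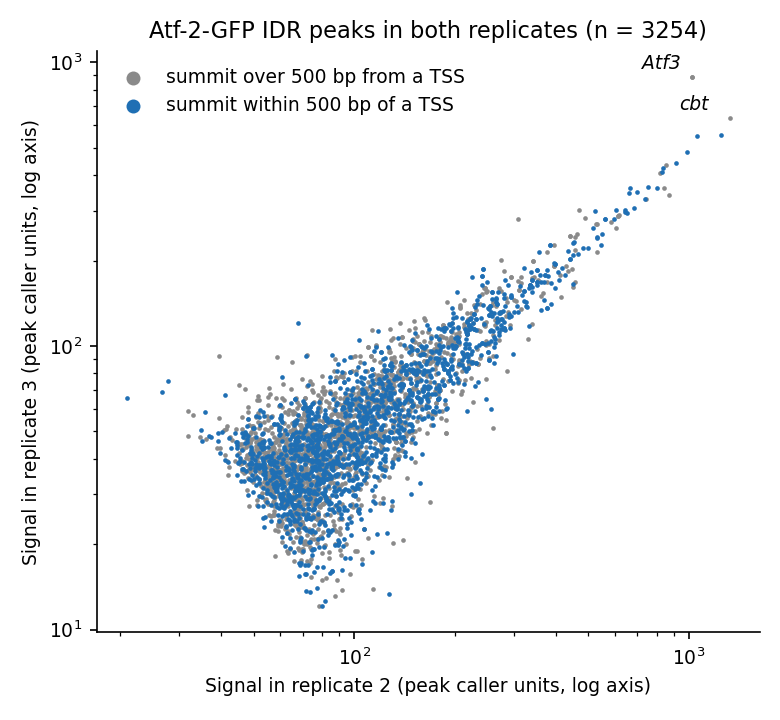
Signal of each IDR peak in replicate 2 (horizontal, log axis) and replicate 3 (vertical, log axis) for the 3254 peaks found in both, in the peak caller's units. Points are peaks, coloured by distance to the nearest protein-coding TSS. The peak near cbt ranks 1 in replicate 2 and 2 in replicate 3, and that near Atf3 ranks 4 and 1 (Spearman's rho 0.70 across peaks).

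Among the genes nearest to the 20 strongest peaks, 13 had the summit within 500 bp of a TSS. These promoter summits lay at CG14100 (signal 1798), px (1596), Chro (1463), Ugalt (1351), Art3 (1260), PNPase (1234), ph-p (1143), mRpL41 (1112), CG1888 (1060), CenG1A (1049), larp (1024), CG31145 (1012) and Tcs5 (994). Chro encodes a chromodomain protein of interbands, Ugalt a UDP-galactose transporter, Art3 an arginine methyltransferase, ph-p a Polycomb group protein, mRpL41 a mitochondrial ribosomal protein and larp a La-related RNA-binding protein. The Chro summit, on chromosome 3L at 22878883, lay in its 5′ UTR, as did those of PNPase and CG1888, while the px summit, on 2R at 22514293, lay in an intron 194 bp from a TSS. The 7 other summits were near cbt, Atf3, Lk6, CG11050, CG13323, CG4004 and HmgZ. The summit near Lk6, which encodes a kinase of the translation factor eIF4E, was intronic and 969 bp from its TSS, and that nearest to CG13323 was 11915 bp from it and intergenic. None of the 20 had a CRE within 100 bp of the summit.

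Atf3 carried a cluster of peaks. Within 2000 bp of the gene, which is on the minus strand, 5 summits lay in 3 intervals near its upstream end. The highest promoter summit, at 1275457 on chromosome X, was 173 bp from the TSS and had a signal of 841 pooled, 560 in replicate 2 and 280.0 in replicate 3. The strongest summit, at 1276740, was 1456 bp from the TSS and intergenic. A weaker intronic summit at 1273100 had a signal of 93.3. None of the 5 had a CRE within 100 bp.

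**Figure D2:**
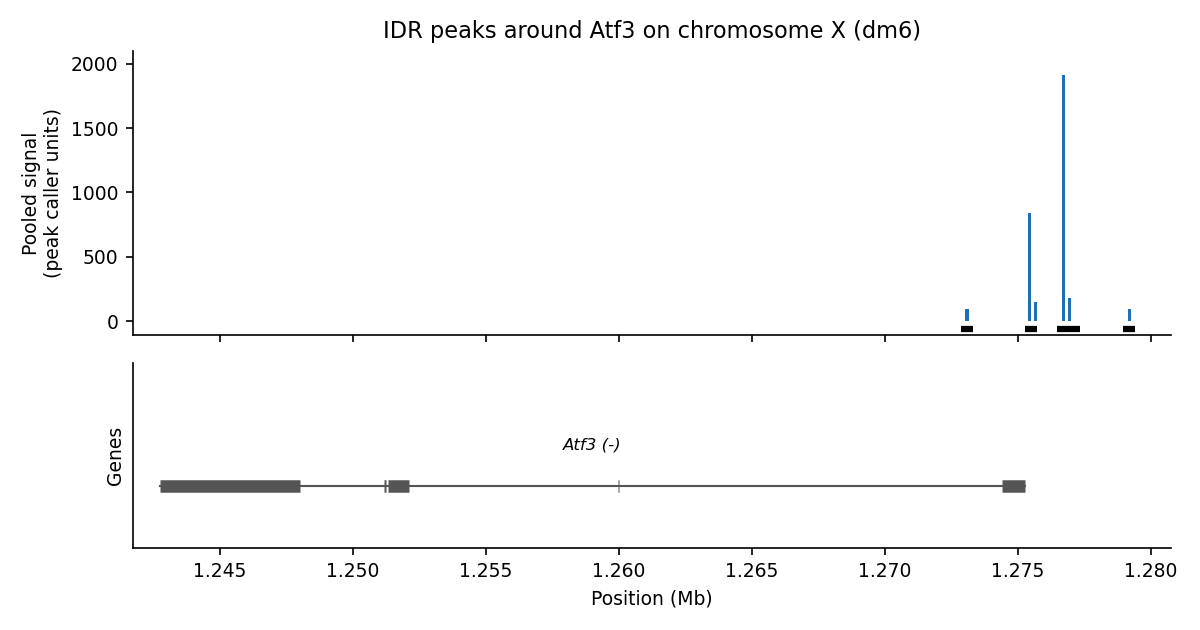
IDR peaks around Atf3 on chromosome X of build dm6, position in Mb. Blue bars are summits with their pooled signal in the peak caller's units, black bars are peak intervals, and the lower panel shows the exons (boxes) and introns (line) of Atf3, transcribed from right to left. The summits of 1913 and 841 lie upstream of the gene's TSS.

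Peaks were concentrated at promoters and almost missing from coding exons. Of the 3265 summits, 1616 (49.5%, interval 47.8 to 51.2%) lay within 500 bp of a protein-coding TSS, against a mean of 11.5% in 1000 random placements (range 9.65 to 13.4%), a 4.30-fold difference (one-sided permutation p = 0.001, the smallest the placements can give). Only 16 summits (0.490%, interval 0.280 to 0.795%) lay in coding exons, against a mean of 16.7% in random placements (one-sided permutation p = 0.001, the smallest they can give). Without replicate 2 the coding share was 1.93%, and without replicate 3 it was 0.398%. In the 25978 pooled regions that overlapped no IDR peak, 23.0% of summits lay in coding exons and 23.6% within 500 bp of a TSS. Introns held 45.7% of IDR summits (41.7% of random positions), intergenic sequence 40.0% (31.4%), 5′ UTRs 9.56% (3.28%), 3′ UTRs 1.26% (5.05%) and noncoding exons 3.00% (1.65%). Promoter peaks had a median signal of 135 and the 1649 distal peaks one of 127. The share of coding exons in the pooled list was 0.4% in the 1000 strongest regions, 7.9% in those ranked 5001 to 6000 and 28.3% in the weakest 1000.

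**Figure D3:**
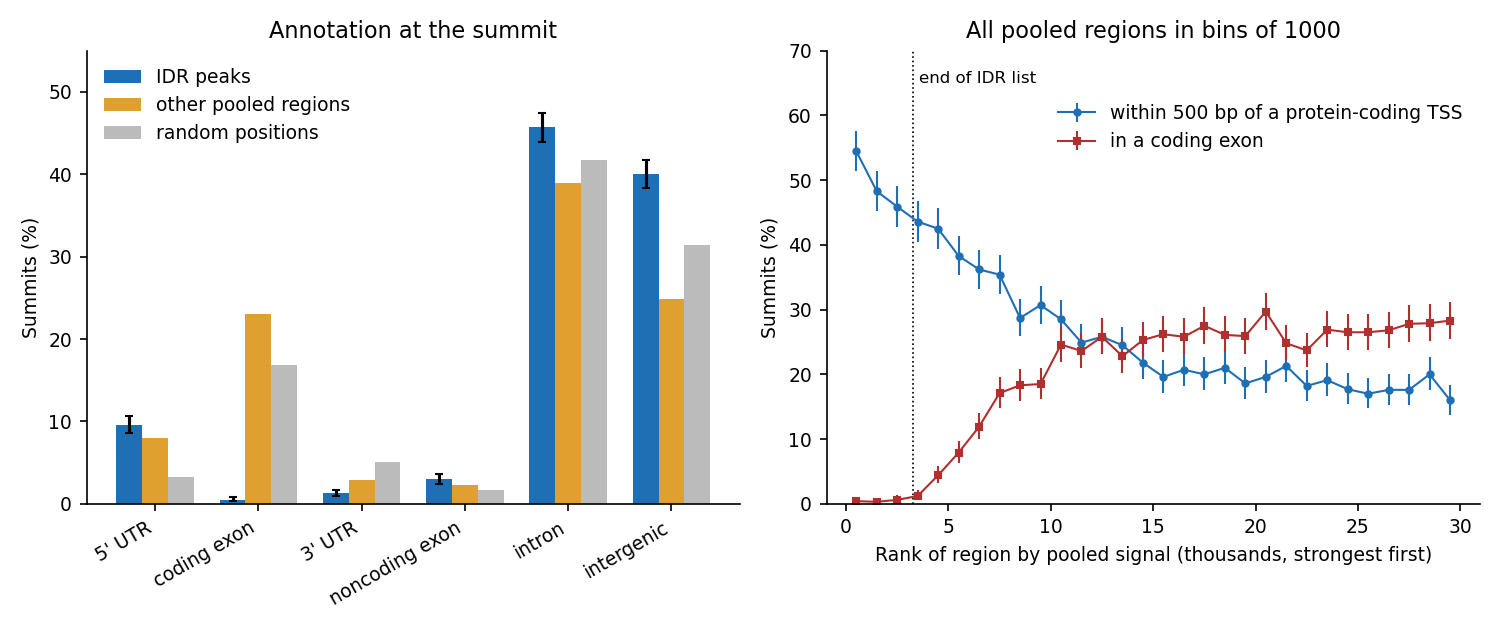
Left, share of summits (%) by annotation for the 3265 IDR peaks (bars with 95% exact intervals), the 25978 other pooled regions and random positions. Right, share of summits (%) near a TSS and in coding exons for the 30000 pooled regions in bins of 1000 by signal, with 95% exact intervals. Coding exons held 0.490% of IDR summits and 28.3% of those in the last bin.

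The X chromosome carried 617 IDR peaks, or 26.2 per Mb, against 24.0 per Mb on the autosomes, a ratio of 1.09 (two-sided exact binomial p = 0.0507). Chromosome 2L had 25.8 peaks per Mb, 3R 24.2, 3L 23.4, 2R 23.4 and the small chromosome 4 had 11.1 (15 peaks). Relative to the other pooled regions, the odds of an IDR peak lying on X were 1.27 times as high (Fisher's exact test, p = 1.22e-06). The whole pooled list was itself sparser on X, with a ratio by length of 0.889, which raises this comparison. The ratio by length was 0.989 in the strongest regions of replicate 3 alone and 1.09 in those of replicate 2 alone, where the exact binomial p was 0.0455.

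The CRE was not enriched at Atf-2-GFP summits. It occurred in 16 of 3265 windows of 100 bp on each side of the summit (0.490%, interval 0.280 to 0.795%) and in 29 of 6293 flanking windows 2000 bp away (0.461%, interval 0.309 to 0.661%), a ratio of 1.06 (Fisher's exact test, adjusted p = 1). In promoter peaks against promoters without a peak its ratio was 2.46 (exact test, adjusted p = 0.0919). Against flanks the CRE ratio was 1.78 without replicate 2 and 0.837 without replicate 3 (exact test, adjusted p = 0.101 and 0.8005). Sites of other bZIP families gave ratios of 1.26 for the AP-1 site (adjusted p = 0.310 by the same exact test), 1.01 for the CEBP-ATF site TGATGCAA, 1.28 for the CNC-Maf site, found in 2 peaks, and 0.551 for the CRE variant TGACGTAA. The PAR bZIP site TTACGTAA, bound by factors such as vri, occurred in 16 peaks (0.490%) and 8 flanks (0.127%), a ratio of 3.85 (exact test, adjusted p = 0.00520), but the strongest regions of each replicate alone gave no call, with ratios of 2.28 without replicate 2 and 2.36 without replicate 3 (exact test, adjusted p = 0.101 and 0.205). A scrambled CRE gave 0.710.

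Sites of promoter factors with no known tie to Atf-2 were more frequent at the summits. The DRE, TATCGATA, the site of the promoter factor DREF, occurred in 122 peaks (3.74%) and 31 flanks (0.493%), a ratio of 7.58 (exact test, adjusted p = 3.14e-30). The M1BP site GGTCACACT occurred in 43 peaks (1.32%) and 23 flanks (0.365%), a ratio of 3.60 (exact test, adjusted p = 1.85e-06). The Zelda site CAGGTAG, bound by an activator of the early embryonic genome, was less frequent at summits (0.735%) than in flanks (1.51%), a ratio of 0.487 (exact test, adjusted p = 0.00359), but the call was lost against flanks matched on GC content (ratio 0.786, exact test, adjusted p = 0.621), without replicate 2 (0.6004) and without replicate 3 (0.679). The GAGA site (ratio 1.09) and the E-box (0.896) did not pass the test, although with 250 bp on each side of the summit the GAGA ratio was 1.93 (exact test, adjusted p = 7.85e-25). DRE sites were in 7.24% of promoter peaks and 0.303% of distal ones (exact test, adjusted p = 2.93e-29), and M1BP sites in 2.41% and 0.243% (exact test, adjusted p = 6.46e-08). In promoter peaks against promoters without a peak the M1BP ratio was 0.928 (exact test, adjusted p = 0.804). Promoters without a peak have no summit to centre a window on, so position in the promoter may enter this ratio. Counted by gene, 20.8% of the 816 genes with an M1BP site within 100 bp of a TSS had a promoter peak. Other genes had one in 14.6% of cases (exact test, adjusted p = 7.84e-06). Of the 43 peaks with an M1BP site, 39 are promoter peaks. The PAR bZIP and Zelda calls each failed in 4 of 8 alternatives and the M1BP call in 2, while the DRE ratio stayed between 1.56 and 8.29 in all 8, past the threshold each time.

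**Figure D4:**
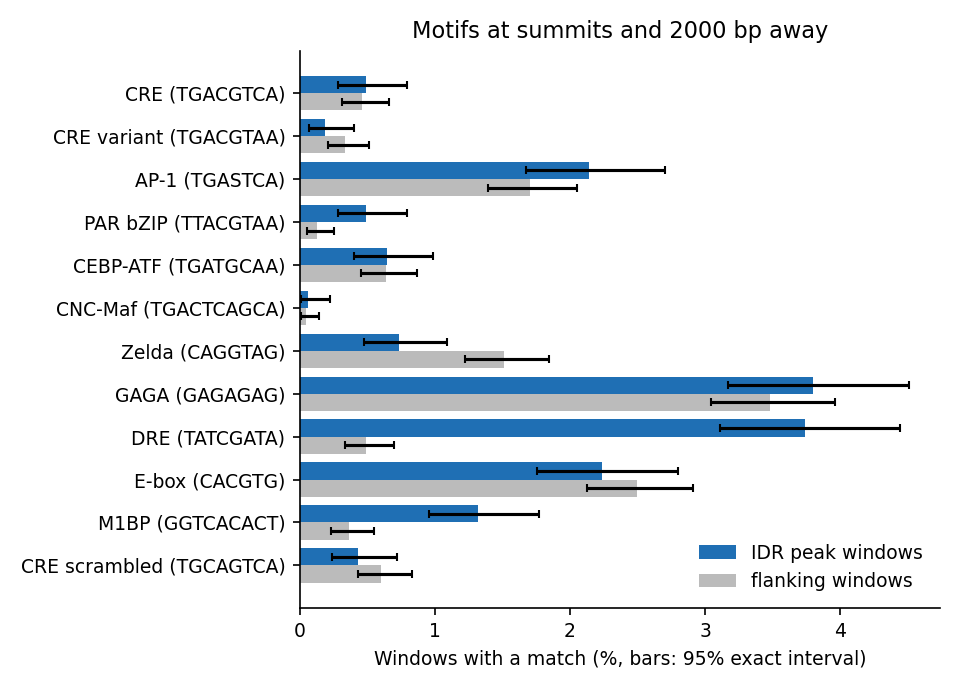
Share (%) of 201 bp windows with a match to each of 12 motifs at the 3265 IDR summits (blue) and in 6293 flanking windows (grey), with 95% exact intervals. DRE (3.74% against 0.493%) and M1BP (1.32% against 0.365%) stand apart, and the CRE bars (0.490% against 0.461%) overlap.

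A scan of all 32896 8-mers (each with its reverse complement) found 1718 enriched and 2053 depleted at adjusted p under 0.05 by the exact test, and the CRE ranked 29611. Its rank varied with the setting, from 1690 in promoter peaks against promoters without a peak, 6635 without replicate 2 and 7196 against flanks matched on GC content to 24715 without replicate 3, and it passed the threshold in none of 7 alternatives (smallest adjusted p = 0.2508, exact test). The 10 leading 8-mers were CACAGTGG (5.05% of peaks against 0.715% of flanks), ATCGATAG (3.74% against 0.461%), CACTGAGA (4.10% against 0.604%), CACTGTGC (4.93% against 0.969%), TATCGATA (3.74% against 0.493%), ACAGTGGG (3.89% against 0.731%), TTTAAAAA (10.5% against 4.70%), CAACACTG (3.31% against 0.524%), AAAAAAAT (12.0% against 5.93%) and TACACTGA (3.49% against 0.683%). ATCGATAG, TATCGATA and CAACACTG were mostly in promoter peaks (7.43%, 7.24% and 5.76%) and rare in distal ones (0.121%, 0.303% and 0.910%). CACTGAGA and TACACTGA showed the opposite, with 1.61% and 1.49% of promoter peaks against 6.55% and 5.46% of distal peaks. For these 5 the difference passed the exact test (largest adjusted p = 7.08e-10). CACAGTGG was in 4.64% of promoter and 5.46% of distal peaks (exact test, adjusted p = 0.428). Peak windows had a GC content of 37.0% ± 6.41 (SD, n = 3265) and flanks one of 43.5% ± 9.45 (SD, n = 6293), and the number of enriched 8-mers was 160 against 2565 flanks matched on GC content. Part of that fall comes from the smaller background, since 5 random draws of 2565 flanks without matching gave 861 to 970. Without replicate 2 the scan found 1116 enriched 8-mers, 954 of them shared with the main scan, and without replicate 3 it found 1762.

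Among the peaks, no difference in the CRE was detectable by peak strength, by distance to the summit, or between promoter and distal peaks. It was in 3 of the 816 strongest and 5 of the 816 weakest peaks (ratio 0.6, Fisher's exact test, p = 0.726). Of 43 CRE matches within 250 bp of a summit, 8 (18.6%) lay within 50 bp, where 20% of the span lies (exact binomial p = 1). CREs were in 10 of 1616 promoter peaks and 6 of 1649 distal peaks (ratio 1.70, Fisher's exact test, p = 0.327). Counts this small could not show a modest difference, and they moved with the peak list. Without replicate 3 the ratio of strong to weak peaks was 1.5. Without replicate 2, 28.3% of matches lay within 50 bp (exact binomial p = 0.194). Counted by gene, a promoter peak was at 15 of 49 genes with a CRE within 100 bp of a TSS. That is 30.6%, against 14.9% of other genes (exact test, adjusted p = 0.00874). Genes with GAGA, DRE or M1BP sites there passed the same test.

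Genes for cytosolic ribosomal proteins carried promoter peaks far more often than other genes. A summit lay within 500 bp of a TSS of 57 of 92 such genes (62.0%, interval 51.2 to 71.9%), against 14.6% of other protein-coding genes, a ratio of 4.24 (Fisher's exact test, adjusted p = 1.45e-23). Among genes with any pooled region near a TSS the ratio was 2.36 (67.9% against 28.8%, exact test, adjusted p = 5.25e-12). The strongest were at RpS27 (signal 464.5), RpL41 (414), RpL7 (408) and RpL23A (353). Mitochondrial ribosomal protein genes had peaks in 20 of 73 (27.4%, ratio 1.84, exact test, adjusted p = 0.0211), led by mRpS10 (1260), mRpL41 (1112), mRpS23 (1049) and mRpL23 (618.5). The mRpS10 peak is the one named above at Art3 and the mRpS23 peak the one at CenG1A, each summit lying within 500 bp of a TSS of both neighbours. In all, 2081 of 13945 protein-coding genes (14.9%) had a promoter peak. The mitochondrial call was lost in 3 of 7 alternatives, the lowest ratio being 1.14 (exact test, adjusted p = 0.956) among genes with any pooled region near a TSS. Of 26 lists, 3 were above and 5 below the other genes.

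The bZIP family was the third list above the rest, with 8 of 21 genes (38.1%, interval 18.1 to 61.6%, ratio 2.56, exact test, adjusted p = 0.0261). Its members with a promoter peak were Atf3 (841), REPTOR (366), Irbp18 (343), CrebA (146), Atf-2 itself (134), cnc (126), Xbp1 (126) and vri (118). REPTOR acts downstream of TOR signalling, Irbp18 is a partner of Atf4, cnc directs the oxidative stress response, and Xbp1 the unfolded protein response. The peak at Atf-2, on chromosome 2R at 24869782 to 24870217, was intergenic with its summit 108 bp from the TSS, and had a signal of 76.3 in replicate 2 (rank 2021) and 56.6 in replicate 3 (rank 1174). The Irbp18 summit lay in the 3′ UTR of the neighbouring CG33947. The bZIP call failed in 4 of 7 alternatives, the lowest ratio being 1.71 (adjusted p = 0.410, exact test) among genes with any pooled region near a TSS.

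The p38 and JNK lists gave no call. In the list of the p38 pathway and Atf-2 itself, 3 of 8 genes had a promoter peak (37.5%, exact test, adjusted p = 0.270), among them Atf-2 (134) and p38a (122). In the JNK and AP-1 pathway, 2 of 18 did (11.1%, exact test, adjusted p = 1), at Mkk4 (674.5, rank 49) and Tak1 (162), both kinases of the JNK cascade. The summit counted for Mkk4 was 178 bp from its TSS and closer to that of the neighbouring SLIRP2 (110 bp). Stress lists gave no call either, with 6 of 23 for endoplasmic reticulum stress, among them Herp (328) and Ire1 (244), 4 of 17 for heat shock, led by Hsp27 (258) and Hsp83 (246), and 3 of 17 for oxidative stress. These counts rest on few genes: without replicate 2 oxidative stress had 6 of 17 (35.3%, exact test, adjusted p = 0.06995), and without replicate 3 the p38 list had 4 of 8 (exact test, adjusted p = 0.0616). Immunity had 3 of 24, led by imd (355), metabolism 5 of 22, circadian clock 3 of 10, proteasome 6 of 48 and vacuolar ATPase 9 of 33.

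Genes for chemosensory receptors and for cuticle proteins carried no promoter peaks. Cuticle protein genes had 0 of 102, which allows a share of up to 3.55% with genes counted as independent (exact test against other genes, adjusted p = 1.86e-06). No share at random positions was drawn for the lists, so they are not shown to lie below random placement. Odorant receptors had 0 of 59, gustatory receptors 0 of 60 and ionotropic receptors 0 of 60 (largest adjusted p = 0.000722, exact test), and male accessory gland genes 1 of 47 (adjusted p = 0.0261, exact test), at Sfp26Ad (110.5), whose summit lay in the 5′ UTR of Gpdh1. The accessory gland call was lost in 3 of 7 alternatives, and its direction turned to a ratio of 1.14 (3 genes, exact test, adjusted p = 1) among genes with any pooled region near a TSS. Embryonic patterning genes had 1 of 25 (bcd, 229), Hox genes 0 of 8, and markers of fat body and blood cells 0 of 12. Muscle, nervous system, gut, epidermis and trachea, and germline markers had 1 each, at sls (340.5), elav (423), fkh (219), bnl (108) and piwi (85.1). Such small counts moved with the peak list: without replicate 2, muscle had 3 of 13 (ratio 1.64, where it was 0.515), epidermis and trachea 2 of 13, patterning 2 of 25 and germline 0 of 8, none past the threshold. Among genes with any pooled region near a TSS the receptor lists kept 2 to 10 members, and their calls were lost while that of the cuticle list was not (exact test, adjusted p = 0.0240). The same happened with the stronger 1632 IDR peaks, where the smallest adjusted p of the receptor lists was 0.0574 and that of the cuticle list 0.00287 (exact test).

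**Figure D5:**
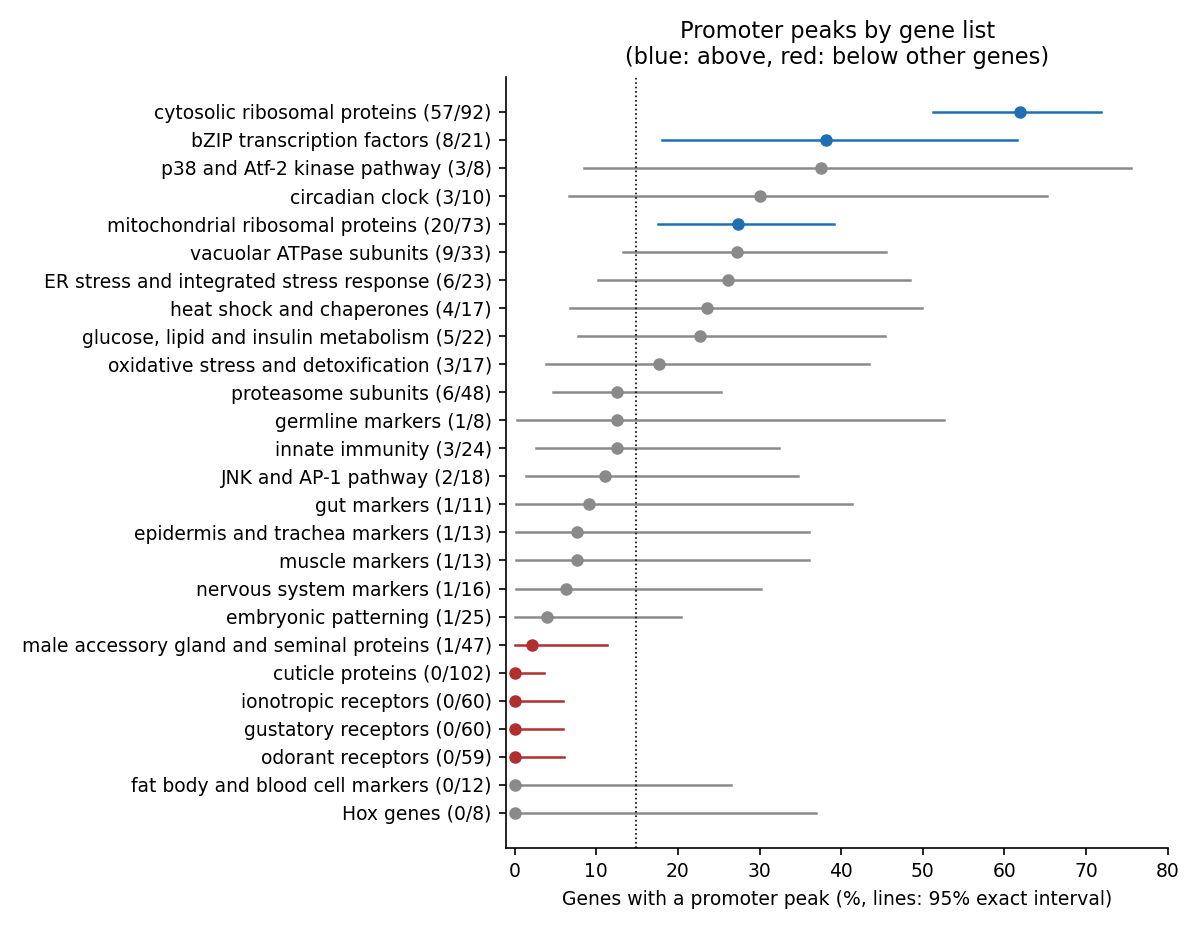
Share of genes (%) with a summit within 500 bp of a TSS in each of 26 lists, with the count and list size beside the name; points are shares, lines 95% exact intervals and the dotted line the share of all protein-coding genes, 14.9%. Blue lists lie above and red lists below the other genes at adjusted p under 0.05. Cytosolic ribosomal proteins reach 62.0%.

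Among noncoding genes, tRNA genes had a summit within 500 bp of their start in 10 of 290 cases (3.45%), snoRNA genes in 12 of 269 (4.46%) and pre-miRNA genes in 6 of 260 (2.31%), against 13.1% of protein-coding genes measured at the same outer start. All 3 were lower than protein-coding genes by Fisher's exact test (largest adjusted p = 4.79e-06). Their shares were not set against random positions, so a depletion below random placement is not shown. The tRNA ratio was 0.2625, and 0.4235 without replicate 2 (exact test, adjusted p = 0.000162). Spliceosomal and other snRNA genes had 7 of 32 (21.9%, exact test, adjusted p = 0.182). Within 1000 bp the snoRNA ratio was 0.997, where it was 0.340 within 500 bp.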

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

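Of 178 recomputed values, 123 kept their direction and side of the threshold or stayed within their allowed spread. Settings chosen after seeing the data were the GC-matched flanks, promoter peaks against promoters without a peak, the overlap on dm3 and all those of the coding share. The promoter share ranged from 39.3 to 58.9% and passed in all 7 settings, and the coding share from 0.368 to 1.93% in all 4. Using only the stronger 1632 IDR peaks, the overlap in both replicates was 77.4%, rho 0.73, motifs enriched 1 (3 in the main setting), 8-mers 645 (1718), lists past the threshold 2 (8), the CRE ratio 0.793 and the CRE ratio of strong to weak peaks 1.5. That setting has fewer peaks to test. With 50% reciprocal overlap the share in both replicates fell to 59.2% and rho to 0.58; with the 2N strongest regions of each replicate the share was 94.6%, and over all pooled regions rho was 0.65. Leaving out replicate 2 or 3, the X ratio was 0.989 or 1.09, the CRE ratio 1.78 or 0.837, the CRE ratio of strong to weak peaks 0.625 or 1.5, the share of CREs near the summit 28.3 or 19.5%, and enriched 8-mers 1116 or 1762. The X odds ratio was 1.27 against other pooled regions and 1.23 on dm3 by the same comparison, both past the threshold. Against other pooled regions 3012 8-mers were enriched, with 50 bp windows 700, against GC-matched flanks 160 (fewer windows) and in promoter peaks against promoters without a peak 149. In the last setting 1 motif was enriched, the M1BP ratio was 0.928 and the CRE ratio 2.46 (10 of 1616 promoter peaks, exact test, adjusted p = 0.0919), and against GC-matched flanks the CRE ratio was 0.629. With 50 bp windows the CRE ratio of strong to weak peaks was 2. Among genes with any pooled region 2 lists passed, and the male accessory gland ratio was 1.14, from 3 genes. For the GC-matched flanks, random draws of as many unmatched flanks gave 861 to 970 enriched 8-mers, so fewer windows account for only part of that fall. The cause of the other changes was not tested. The CRE ratio at summits passed the threshold in none of 8 settings, and no paired analysis was possible because there was only 1 group. Depth limits every statement on weak peaks, since it is unknown.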

Other observations

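All tests in this part compare peaks, sequences or genes within these lists. Chosen after seeing the result were the count of CREs in the 100 strongest peaks and the share of windows with near CRE matches. So were the promoter comparison of 8-mer groups, and the GC-matched and promoter-matched backgrounds. The comparison of ribosomal protein genes with 3 other lists together was chosen then too. Some genes collected many IDR peaks within 2000 bp of their span. CG1677 on chromosome X had 15, kirre, a cell adhesion gene, 14 over 394 kb, ush 13 over 64.3 kb, Raf, the kinase upstream of MEK, 12 over 48.4 kb, sbb 11, and Hr4 and CHES-1-like 10 each. Bacc, 5.53 kb long, had 6, the strongest of which also counted for the overlapping Pgk. Length was not accounted for: kirre had 0.352 peaks per 10 kb, where X as a whole had 26.2 per Mb. CG1677 was 124.7 kb long and had 1.165 per 10 kb. Cytosolic ribosomal protein genes also stood above the mitochondrial ribosomal, proteasome and vacuolar ATPase lists together. A promoter peak was at 62.0% of them against 35 of 154 (22.7%, ratio 2.73, Fisher's exact test, p = 1.12e-09). The lists were set by gene symbol, and 84 of 92 cytosolic ribosomal genes had any pooled region near a TSS. In the other lists 60 of 73, 28 of 48 and 18 of 33 did. Among such genes a promoter peak was at 67.9% against 33.3%, 21.4% and 50%, so part of the ratio goes with which genes gave any region. Peaks at ribosomal protein genes had a median signal of 160.5, against 132 for all IDR peaks.

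The first pattern is that the CRE was not enriched in the peaks. Of the 100 strongest peaks, 2 had a CRE anywhere in their interval (interval 0.243 to 7.04%). This argues against a CRE in a large part of the strong peaks. No background share for these intervals was drawn, so weak peaks that hide a modest enrichment cannot be excluded. A difference in GC content is argued against by a ratio of 0.629 with matched flanks (odds ratio interval 0.303 to 1.28). Whether the consensus is too strict stays open, since in the planned test, with the CRE itself left out of the set afterwards, 0 of the 12 8-mers that differ from it at 1 base were enriched, where 0.627 would be expected at the rate of all 8-mers, and the interval of 0 to 26.5% is too wide to decide; pooled, in a test added afterwards, these near matches were 0.976 times as frequent in peaks as in flanks (odds ratio interval 0.774 to 1.22), which argues against enrichment of the whole set but not of a few members. Summits that lie away from the bound site cannot be excluded, since with 250 bp on each side the ratio was 1.04 with an odds ratio interval of 0.694 to 1.56. General recovery of open promoters cannot be told apart from weak direct binding: of 49 genes with a CRE within 100 bp of a TSS, 15 had a peak (30.6%, the highest share of 8 motifs, 2.06 times other genes, odds ratio interval 1.28 to 4.77, exact test, adjusted p = 0.00874), GAGA (26.1%), DRE (22.6%) and M1BP (20.8%) passed as well, the scrambled CRE (17.6%, adjusted p = 0.505), AP-1 (17.9%), PAR bZIP and Zelda did not, and no biological explanation was tested.

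The second pattern is that 8-mers unlike any bZIP site led the scan; of the 50 with the smallest p, 4 were depleted in peaks, and among the enriched ones 18 contained CACTG or its complement, 17 were of A and T only and 5 held a DRE-like core. Copies of mobile elements were not the source for CACAGTGG, since 0.606% of its windows overlapped an annotated element (interval 0.0153 to 3.33%), as did 0.582% of all IDR windows. Promoter sequence in general is argued against for CACAGTGG, found in 5.46% of distal peaks and 0.986% of their flanks (ratio 5.53, exact test, p = 1.80e-19). The 6 CACTG 8-mers among the 10 leading ones were together in 18.7% of distal and 15.35% of promoter peaks. Of these, CAACACTG was mostly in promoter peaks. In promoter peaks against promoters without a peak CACAGTGG was 6.29 times as frequent (odds ratio interval 4.71 to 9.09). There the 6 together were 3.88 times as frequent (odds ratio interval from 3.72). Promoters without a peak have no summit to centre a window on, so these ratios may mix position in the promoter with binding. For the other parts promoter sequence in general cannot be told apart from binding. The same ratio was 1.62 for the DRE-like pair (odds ratio interval 1.41 to 2.03) and 1.37 for the A and T pair (1.29 to 1.68). The DRE-like pair was in 9.96% of promoter peaks, 6.13% of promoters without a peak and 0.762% of the flanks of promoter peaks. A hypothesis left open for the CACTG part, and untested without a list from another tagged factor, is that a sequence-specific protein other than Atf-2 may mark these sites.

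The third pattern is that summits were nearly absent from coding exons. GC content could lower the coding share, but random positions matched to the peaks in GC content (37.0%) lay in coding exons in 6.54% of cases (interval 6.33 to 6.74%), 13.3 times the share of IDR summits (0.490%; 1.93% without replicate 2, for which no matched positions were drawn). Placement of peaks at promoters is not enough either, since 7 of the 1649 distal summits (0.425%, interval 0.171 to 0.873%) lay in coding exons, against 15.7% of random positions over 500 bp from a TSS. The control named in the deposited readme texts was not analysed here, so an uneven control stays open, and no biological explanation was tested.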
